A study of Caenorhabditis elegans with 2 samples.

How the data were processed

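ChIP-seq against CRH-2 was performed on 2 biological replicates of whole L2 larvae, per the labels, and both were placed in 1 group from their descriptions. Whether they came from separate cultures is stated only as a biological replicate number. The authors called regions on each replicate and on both pooled, against a control library whose files were not used here. These went to the irreproducible discovery rate (IDR) procedure, which gave the list called replicated peaks here. The name does not mean that each peak was found in both replicates. Of 5735 peaks on ce11, 5704 overlapped a region in the list of each replicate. The peak caller, the aligner and their versions are not given in the sources used here. No control library was analysed here, so signal at open chromatin could not be set apart from binding.

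The deposited lists are in narrowPeak format on the ce11 and ce10 builds, which were kept apart. The signal of each region is the authors' own value and was used only to describe, rank or filter regions within a list. The −log10 q-value of each region is also the authors' value, per the file headers of the format, and was the same, 4.07, for every replicated peak. The deposited summit offset, another value of the format, gave the summit position. All 5735 replicated peaks on ce11 were identical to the 5735 strongest regions of the pooled list, so IDR set how many regions were kept and not which ones. Depth is unknown, and confidence intervals cover counting error only. Peaks and genes of 1 genome are not biological replicates, so p-values describe these lists. All columns of values used were mapped, with 0 left out for lack of a sample.

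Coordinates were matched to the WBcel235 assembly, the same sequence as ce11, with Ensembl annotation release 115. Results are 1-based. A summit counted as a promoter summit from 1000 bp upstream to 250 bp downstream of the 5′ end of any protein-coding transcript, and otherwise took the first of 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic that applied. Shares were compared with 1000 random placements within chromosomes, where 0.002 is the smallest two-sided p. A gene was bound if a summit lay in its promoter window. The relative signal of a peak is the signal of the strongest overlapping region of a replicate divided by that replicate's median over the peaks.

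The 18 gene lists were matched by symbol, and members with no match among protein-coding genes were left out. Sequence motifs were counted on both strands in windows of 50 bp to each side of 5735 summits and of 11252 positions 300 bp to the side. Trends over signal used 100000 permutations. Fisher's exact tests were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05, and intervals of odds ratios are Woolf's at 95%.

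The text names crh-2 and unc-119, the nearest protein-coding gene of the 20 strongest promoter peaks, up to 3 bound members with the highest signal per list, and by position the 5 strongest peaks in no promoter window. Of the chemoreceptor genes, 1 peak that this rule takes is not reported here. This rule, the lists, the motifs and most alternatives were set before the data were examined. Alternatives changed the build, the overlap, the promoter window, the strictness, the replicates used, the gene assignment, the background and the motif window.

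The tests were run on simulated data. With bound genes drawn at random from 19973, 5% of 200 draws called any list. These draws were independent, while bound genes in the data can share a summit, so this rate need not hold there. A planted list bound at 2 times the usual share was called in 19% of 100 draws with 25 genes, 60% with 50 and 93% with 100, so a miss in a small list says little. With shuffled bases 0 motifs and 0 sequences of 8 bases were called. A CREB palindrome planted in 2% of windows was recovered by both tests. Both sets of windows were shuffles of the summit windows, so their GC content was equal. They cannot show what a GC difference, such as that between summits and flanks, does to the calls. Peaks placed at random gave a promoter p under 0.05 in 7% of 100 sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.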

Results

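Binding of CRH-2, a basic leucine zipper (bZIP) factor of the CREB family in the nematode Caenorhabditis elegans, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L2 larvae of mixed sex. The strain carried a transgene in which crh-2 ends in a GFP-FLAG tag, in an unc-119 mutant background. The labels give 1 group of 2 biological replicates, so no condition was compared with another, and the questions answered here are where the tagged factor was found and how well the replicates agree. The list of replicated peaks on the ce11 build held 5735 regions with a median width of 376 bp. Their pooled signal ran from 62.3 to 1625 with a median of 103. The pooled list and the list of each replicate held 30000 regions each, and were deposited as peaks and background, the input to IDR. Read depth is not known from these files, so the number of regions in a list is no measure of depth.

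The 3 strongest peaks lay in the promoter windows of cdc-48.1, puf-9 and hsp-3. The first by signal, 1625, lay 165 bp upstream of cdc-48.1, an AAA ATPase that extracts proteins for degradation, at II 10563424 to 10563721. The second, with a signal of 1616, lay 283 bp upstream of puf-9, a Pumilio-family RNA-binding protein, at X 5841097 to 5841516. The third, with a signal of 1593, lay 62 bp upstream of hsp-3, an endoplasmic reticulum (ER) chaperone of the BiP family, at X 6091994 to 6092413. In units of each replicate's own median over the peaks, cdc-48.1 had a relative signal of 15.3 ± 0.0355 (SD, n = 2), puf-9 of 14.9 ± 0.474 (SD, n = 2) and hsp-3 of 14.8 ± 2.84 (SD, n = 2). These 3 peaks took ranks 1 to 3 in both replicates, although in a different order.

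The remaining strongest promoter peaks included iff-2, a translation factor of the eIF5A family, at 13.1 ± 1.67 (SD, n = 2), and the ribosomal protein gene rpl-3 at 11.4 ± 1.56 (SD, n = 2). A peak at I 7021234 to 7021606 lay in the windows of both ubql-1, a ubiquilin, and pdi-3, a protein disulfide isomerase, and had a relative signal of 10.6 ± 1.14 (SD, n = 2). A peak at IV 4749921 to 4750218 was shared by Y17G9B.5 and rpl-20, at 10.6 ± 0.17 (SD, n = 2). Between 8 and 10 times the median lay tasp-1, rpl-35, Y25C1A.8, the histone gene his-37, crt-1, which encodes calreticulin, nspc-17 and rpl-15. The other genes of the 20 strongest promoter peaks were Y41D4A.4, xbp-1, serp-1.1, H41C03.3, cox-5A and egg-5, with relative signals from 6.66 ± 0.152 (SD, n = 2) at egg-5 to 7.5 ± 1.03 (SD, n = 2) at xbp-1, the transcription factor of the unfolded protein response. A summit in a shared window does not tell which of its genes is the target. Other named genes, here and in the lists below, also shared their summit with another gene, and not every such case is named.

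No region of any list lay at the tagged gene itself. crh-2 (II 5179026 to 5187569, minus strand) and 1000 bp to each side held 0 regions in the replicated, pooled and both replicate lists. unc-119 (III 10902641 to 10908935, plus strand), the gene mutated in the strain, held 2 replicated peaks. The stronger had a signal of 155, rank 1450 of 5735, and the strongest region there had rank 1839 in replicate 1 and rank 1110 in replicate 2. The copy number of either locus in the strain was not measured here.

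The replicates shared most of their strong regions. Of the 5735 replicated peaks, 89.2% (Wilson 95% interval 88.4 to 89.98) overlapped one of the 5735 strongest regions of replicate 1 by at least 1 bp, and 87.6% (86.7 to 88.4) one of replicate 2. Both held for 4455 peaks (77.7%) and neither for 53. Random placement within chromosomes gave means of 4.07% and 4.05%, and at most 5.0% in 1000 placements. The replicated list is made from the pool of both libraries, so these shares are not independent of it. Set directly against each other, 78.3% (77.2 to 79.3) of the strongest regions of replicate 1 overlapped one of replicate 2, against at most 4.8% in random placements. Across 5704 peaks measured in both, Spearman's rho was 0.734 and Pearson's r of the log2 signal was 0.803. These correlations are across peaks, which are not independent replicates. Some peaks overlap each other, since merging overlaps left 5621 regions. Overlapping peaks can take the same region of a replicate, so some values are counted more than once. Relative signals lay within 2-fold of each other at 93.9% of peaks, and the log2 ratio had an SD of 0.51.

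**Figure D1:**
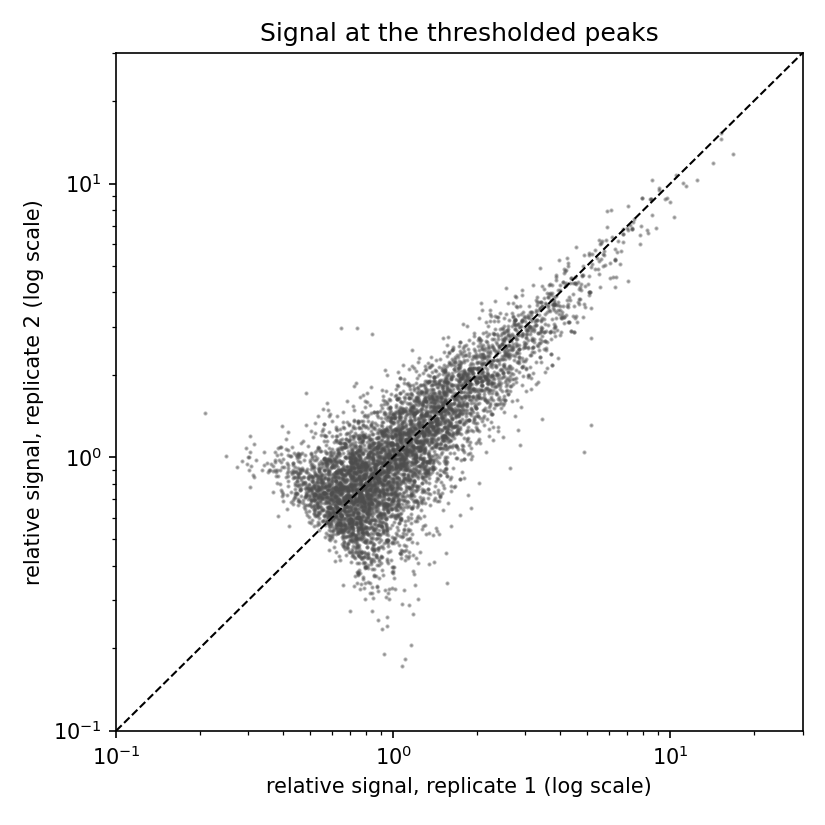
Relative signal of each replicated peak in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), each divided by that replicate's median over the peaks, with 1 point per peak and a dashed line of equal values. The 5704 points follow the line with a Spearman's rho of 0.734.

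Peaks were concentrated in promoters of protein-coding genes and rare in coding exons. Of the 5735 summits, 3309 (57.7%, Wilson 95% interval 56.4 to 59.0) lay from 1000 bp upstream to 250 bp downstream of an annotated 5′ end, against a mean of 26.7% in random placements (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Coding exons held 70 summits (1.22% against 18.4%), 3′ UTRs 61 (1.06% against 2.39%) and introns 763 (13.3% against 27.7%), all at permutation adjusted p = 0.0028. Exons of non-coding RNAs held 261 (4.55% against 2.71%, permutation adjusted p = 0.0028). Intergenic sequence held 1252 summits (21.8% against 21.7%, permutation adjusted p = 0.891) and 5′ UTRs outside promoter windows 19 (0.331% against 0.372%, permutation adjusted p = 0.834). Many worm transcripts are trans-spliced, so an annotated 5′ end need not be the site where transcription starts.

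Promoters of X-linked genes held peaks about as often as autosomal ones. A peak lay at 562 of 2731 X-linked genes (20.6%) and at 3295 of 17242 autosomal genes (19.1%), an odds ratio of 1.10 (95% interval 0.992 to 1.21, Fisher's exact test, two-sided p = 0.0719). In the strongest regions of the single replicates this difference passed the threshold, with an odds ratio of 1.11 (Fisher's exact p = 0.0486) in replicate 2 alone and 1.14 (Fisher's exact p = 0.00909) in replicate 1 alone, and among the 2867 strongest peaks it was 1.02 (Fisher's exact p = 0.794). Peaks per Mb ranged from 43.7 on V to 69.7 on III, with 65.9 on X. Peaks outside promoter windows made up 604 of 1167 peaks on X (51.8%) and 1822 of 4568 on the autosomes (39.9%), an odds ratio of 1.62 (Fisher's exact p = 3.21e-13). The 5 strongest peaks outside promoter windows were all on X.

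The first of these lay in intergenic sequence at X 11093921 to 11094432, 2762 bp from W02H3.3, with a signal of 1135 and a relative signal of 10.6 ± 0.803 (SD, n = 2). The others lay at X 13700631 to 13701056 (nearest gene adm-2), X 9465701 to 9466059 (ZK899.6) and X 8036135 to 8036689 (C34D10.1), all intergenic, and at X 2996860 to 2997370 in an intron of Y41G9A.17. Their relative signals ran from 8.39 ± 0.701 to 9.42 ± 1.22 (SD, n = 2). Among all 5735 peaks they had ranks 7, 9, 11, 17 and 18. None held any of the 15 sequence motifs tested within 50 bp of the summit.

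Genes of the secretory pathway, the ER and the ribosome held promoter peaks far more often than other genes, and chemosensory receptor genes hardly at all. Of 19973 protein-coding genes, 3857 (19.3%) had a promoter peak. In the main tests the other genes were all the rest of these, not matched on expression, open chromatin or GC content. A raised share therefore cannot be told from signal common to active promoters. Among 18 lists fixed before the data were examined, 9 had a higher and 3 a lower share than all other genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). Cytosolic ribosomal proteins had 70 of 82 genes (85.4%, odds ratio 24.8, 95% interval 13.4 to 45.8, exact adjusted p = 3.76e-37). ER chaperones and the unfolded protein response had 18 of 23 (78.3%, odds ratio 15.1, 5.61 to 40.7, exact adjusted p = 5.99e-09). The secretory pathway had 36 of 47 (76.6%, odds ratio 13.8, 7.02 to 27.1, exact adjusted p = 1.84e-16). Their sizes depended on how peaks were given to genes. With the gene of the nearest 5′ end the odds ratios were 4.58 for ribosomal, 9.91 for ER and 5.87 for secretory genes, with 1 gene per promoter peak 5.61, 12.7 and 7.55, and among the 2867 strongest peaks 39.6, 18.2 and 21.02, and each still passed.

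In the ER list the strongest were hsp-3, pdi-3 and crt-1, the last with a relative signal of 8.96 ± 1.98 (SD, n = 2). Secretory genes included sec-61.G, a subunit of the translocation channel, at 6.01 ± 0.566 (SD, n = 2), copd-1, a coat protein of COPI vesicles, at 5.42 ± 0.571 (SD, n = 2), and the small GTPase gene rab-1 at 4.16 ± 0.658 (SD, n = 2). Among ribosomal protein genes rpl-35 reached 9.32 ± 0.252 (SD, n = 2).

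Other lists of metabolism, stress and regulation were also raised. bZIP transcription factors had 19 of 29 genes bound (65.5%, odds ratio 7.97, exact adjusted p = 2.09e-07), with xbp-1, let-607, a factor of the CREB3 family, at 3.19 ± 0.0178 (SD, n = 2) and atf-4 at 2.8 ± 0.238 (SD, n = 2). Oxidative phosphorylation had 26 of 42 (61.9%, odds ratio 6.83, exact adjusted p = 5.99e-09), led by the cytochrome c oxidase genes cox-5A, cox-6B and cox-5B. The list named cytosolic stress response had 14 of 28 (50%, odds ratio 4.19, exact adjusted p = 0.000412), among them the chaperones hsp-90, hsp-60 and hsp-1. Of these hsp-60 encodes a mitochondrial chaperone, so the list is not cytosolic alone. Heterochronic genes, which time larval development, had 9 of 19 protein-coding members (47.4%, odds ratio 3.77, exact adjusted p = 0.00781), with nhl-2 at 5.28 ± 1.09 (SD, n = 2), ain-1 and lin-28. Of the microRNA members, which were outside this test, lin-4, mir-48 and mir-84 had 0 summits in their promoter windows, mir-241 had 1 at rank 3234, and let-7 was not matched. This call was lost with the promoter window of 500 bp upstream to 100 bp downstream (odds ratio 1.95, exact adjusted p = 0.276), and the odds ratio was 6.69 with 2000 bp upstream to 500 bp downstream, 7.43 by the nearest 5′ end and 5.90 without replicate 1. Oxidative phosphorylation had 10.7 among the 2867 strongest peaks and 4.34 by the nearest 5′ end.

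Intestine markers had 14 of 27 genes bound (51.9%, odds ratio 4.51, exact adjusted p = 0.000275), with act-5, an actin of the microvilli, spl-1 and the peptide transporter gene pept-1. Lipid metabolism had 37 of 98 (37.8%, odds ratio 2.55, exact adjusted p = 6.7e-05), with nhr-49, acs-7 and dgat-2. Among the 2867 strongest peaks neither list passed, with odds ratios of 1.80 (exact adjusted p = 0.303) and 1.79 (exact adjusted p = 0.0572), while by the nearest 5′ end lipid metabolism had 4.02.

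Markers of other tissues did not pass the test against other genes. Bound genes numbered 10 of 31 for neurons (odds ratio 1.99, exact adjusted p = 0.147), 5 of 26 for hypodermis and molting (0.995, exact adjusted p = 1), 5 of 28 for body wall muscle (0.908, exact adjusted p = 1), 16 of 92 for pharynx (0.879, exact adjusted p = 0.89) and 3 of 28 for the germline (0.501, exact adjusted p = 0.437). The bound neuron markers with the highest signal were ric-19, egl-21 and snb-1. Those of the germline were rad-51, nos-3 and cgh-1, those of muscle deb-1, act-4 and unc-112, and those of hypodermis ajm-1, elt-1 and wrt-10. In the pharynx list they were pqn-51, pqn-71 and pqn-59, which entered it by the prefix pqn of their names. That list took in all genes with the prefixes phat, abu and pqn, so not every member need be a marker of the pharynx. The summits of pqn-51, pqn-71 and pqn-59 also lay in the windows of K11D12.14, rocf-1 and taf-4, in that order. The odds ratio of hypodermis was 0.562 without replicate 2 and 0.317 in the 2867 strongest peaks, and that of the germline 0.95 in the strongest peaks and 0.332 by the nearest 5′ end, none of which passed. Histone genes had 13 of 60 bound (odds ratio 1.16, exact adjusted p = 0.749), with his-37, htz-1 and his-61. Neuron markers passed when each peak was given to the gene with the nearest 5′ end (odds ratio 3.13, exact adjusted p = 0.00604) or to 1 gene per promoter peak (2.65, exact adjusted p = 0.0273). Against summits rotated along their chromosomes, bound genes were 3.14 times the mean for neurons (permutation adjusted p = 0.00327), 1.97 times for pharynx (permutation adjusted p = 0.0166) and 3.39 times for histones (permutation adjusted p = 0.012), a comparison with random positions. Reads from near-identical histone copies cannot be assigned with certainty.

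Chemoreceptor genes had 20 of 1292 bound (1.55%, odds ratio 0.0608, 95% interval 0.0391 to 0.0947, exact adjusted p = 3.98e-92). Among the strongest, the window of sri-5 was shared with rsr-1, and srh-2 had a relative signal of 2.79 ± 0.00354 (SD, n = 2). Neuropeptide genes had 6 of 106 (5.66%, odds ratio 0.25, exact adjusted p = 0.000202), with nlp-4, nlp-29 and nlp-24. That list took in all genes with the prefixes flp and nlp, so not every member need encode a neuropeptide. Cuticle collagens had 14 of 176 (7.95%, odds ratio 0.359, exact adjusted p = 0.000103), with col-38, col-71 and col-63. The col-38 summit also lay in the window of the ribosomal protein gene rpl-5, and that of col-71 in the window of Y49F6B.2. Rotating all summits along their chromosomes gave a mean of 12.02 bound collagen and 7.87 bound neuropeptide genes (permutation adjusted p = 0.688 for each), so these lists were low against other genes but not against random positions. Among the 2867 strongest peaks the odds ratios were 0.0902 for collagens, 0.075 for neuropeptides and 0.0401 for chemoreceptors. Collagens had 0.231 without replicate 2, and with 2000 bp upstream to 500 bp downstream neuropeptides had 0.467 and chemoreceptors 0.0934, with neuropeptides at 0.449 by the nearest 5′ end.

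**Figure D2:**
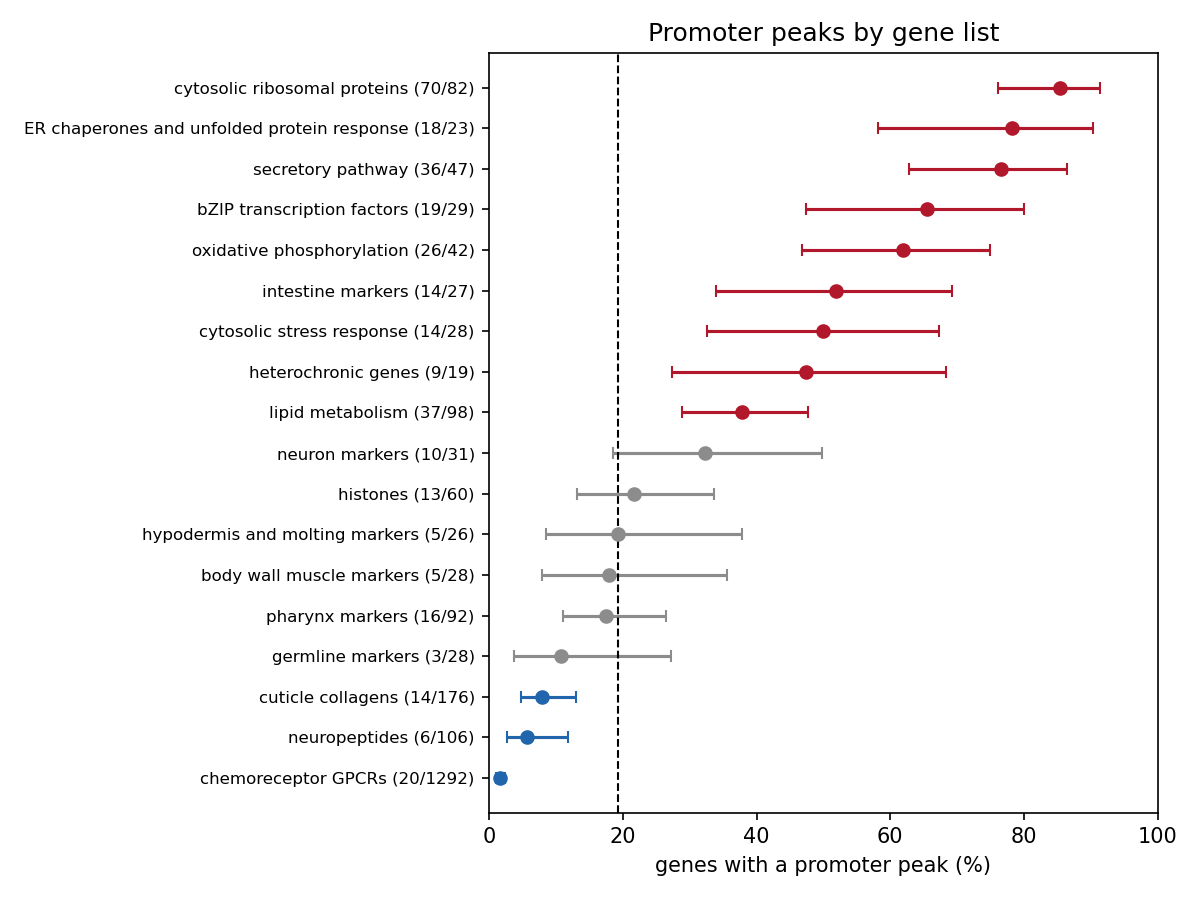
Share of the genes of each list with a promoter peak (horizontal, percent, with Wilson 95% intervals and counts beside each name), in red for lists above and blue for lists below other genes at an adjusted p under 0.05, and grey otherwise. The dashed line marks the 19.3% of all protein-coding genes.

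CREB-type sequences were more frequent at summits than in the flanks, most of all the TGACGTGK site of CREB3 and XBP1 factors. It occurred within 50 bp of 205 summits (3.57%, Wilson 95% interval 3.12 to 4.09) and in 0.347% of flank windows, an odds ratio of 10.7 (95% interval 7.56 to 15.03, Fisher's exact test, exact adjusted p = 3.16e-59). The CREB palindrome TGACGTCA occurred at 74 summits (1.29% against 0.4%, odds ratio 3.26, exact adjusted p = 4.98e-10), and the shorter core TGACG at 1235 (21.5% against 9.94%, odds ratio 2.49, exact adjusted p = 2.34e-89). CACGTGG (odds ratio 4.24, exact adjusted p = 2.11e-33) and the E-box CACGTG (4.83, exact adjusted p = 5.56e-75) were raised as well. So were the repeat GAGAGAGA (8.63, exact adjusted p = 1.61e-95), the GATA site WGATAR (1.71, exact adjusted p = 9.71e-47) and the GC box GGGCGG (2.69, exact adjusted p = 6.3e-22). The CEBP palindrome TTGCGCAA was raised too (2.29, exact adjusted p = 0.0175), a call that was lost without replicate 1 (1.58, exact adjusted p = 0.256). In promoter peaks alone the odds ratio was 4.99 for TGACGTCA, 4.20 for TTGCGCAA and 6.19 for TGACGTGK. Outside promoter windows TGACGTGK had 28.1, while TGACGTCA (1.89, exact adjusted p = 0.0615) and TTGCGCAA (0.782, exact adjusted p = 0.905) did not pass.

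The remaining 6 of the 15 sequences did not pass. These were the AP-1 site TGASTCA (odds ratio 0.973, exact adjusted p = 1), the SKN-1 type site WWTRTCAT (0.906, exact adjusted p = 0.276), the PAR-type palindrome TTACGTAA (1.963, exact adjusted p = 0.296), TGRACTTTG (1.41, exact adjusted p = 0.276) and the composition controls CTACGTAG (0.28, exact adjusted p = 0.324) and AGTCGACT (1.09, exact adjusted p = 1). WWTRTCAT passed as less frequent in the 2867 strongest peaks (0.686, exact adjusted p = 0.00123), without replicate 1 (0.837, exact adjusted p = 0.0339) and in promoter peaks alone (0.803, exact adjusted p = 0.0441), and as more frequent against GC-matched promoters (1.49, exact adjusted p = 6.81e-05). Summit windows had a mean GC content of 43.2% and flanks of 34.7%. Against promoter windows without a peak matched on GC content, TGACGTGK stayed raised (odds ratio 4.79, exact adjusted p = 5.95e-26), while TGACGTCA (1.52, exact adjusted p = 0.0547), TTGCGCAA (1.91, exact adjusted p = 0.165) and GGGCGG (0.991, exact adjusted p = 1) did not pass. TGACG (1.58), CACGTGG (2.24), CACGTG (2.88) and GAGAGAGA (5.12) passed there with smaller odds ratios than against flanks, and WGATAR with a larger one (2.38, exact adjusted p = 1.44e-81).

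**Figure D3:**
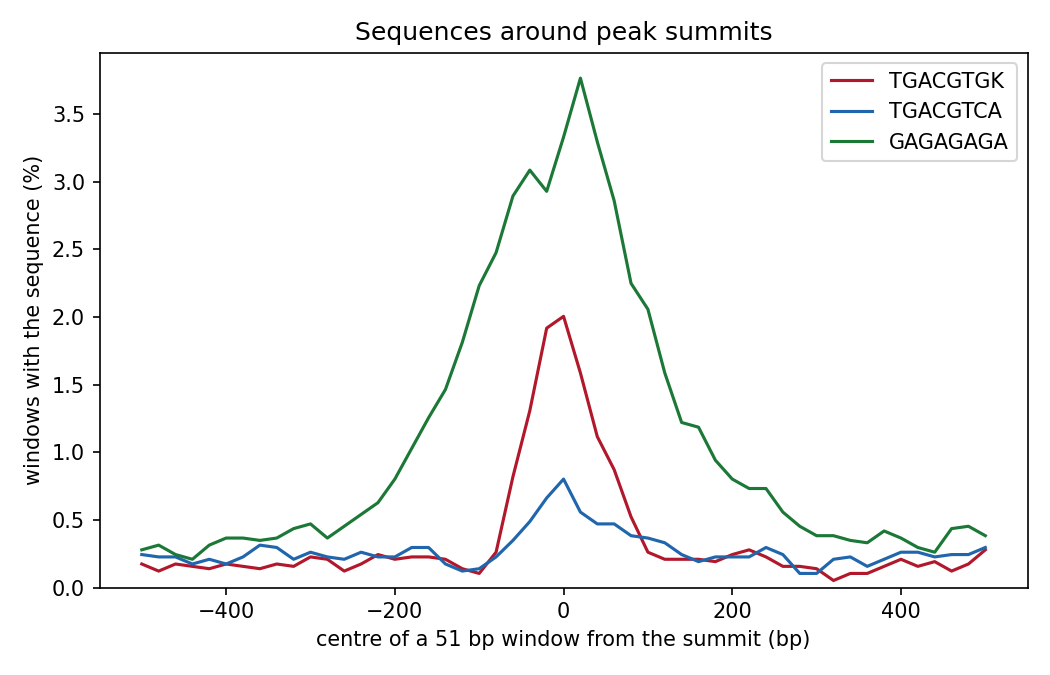
Percent of windows holding TGACGTGK, TGACGTCA or GAGAGAGA (vertical) by the distance of the window's centre from the summit in bp (horizontal), over all replicated peaks. The lines are highest near the summit.

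Stronger peaks held TGACGTGK and TGACG more often. The share with TGACGTGK was 2.01% in the weakest quintile of signal and 6.54% in the strongest, and that with TGACG 19.1% and 27.6% (permutation test, two-sided, adjusted p = 1.5e-05 for each, from the smallest p that 100000 permutations can give). The difference for TGACGTGK was 4.53 percentage points, and 2.35 with windows of 25 bp to each side, where it also passed. TGACGTCA went from 1.22% to 1.83% without passing (permutation adjusted p = 0.647). Mean GC content also rose, from 40.6% to 47.2%. Trends of 2 other sequences were computed after the data were examined. GAGAGAGA rose from 4.71% to 7.5% (permutation p = 0.00024), and the AT-rich GATA site WGATAR fell from 37.7% to 20.3% (permutation p = 1e-05, the smallest that the permutations can give).

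**Figure D4:**
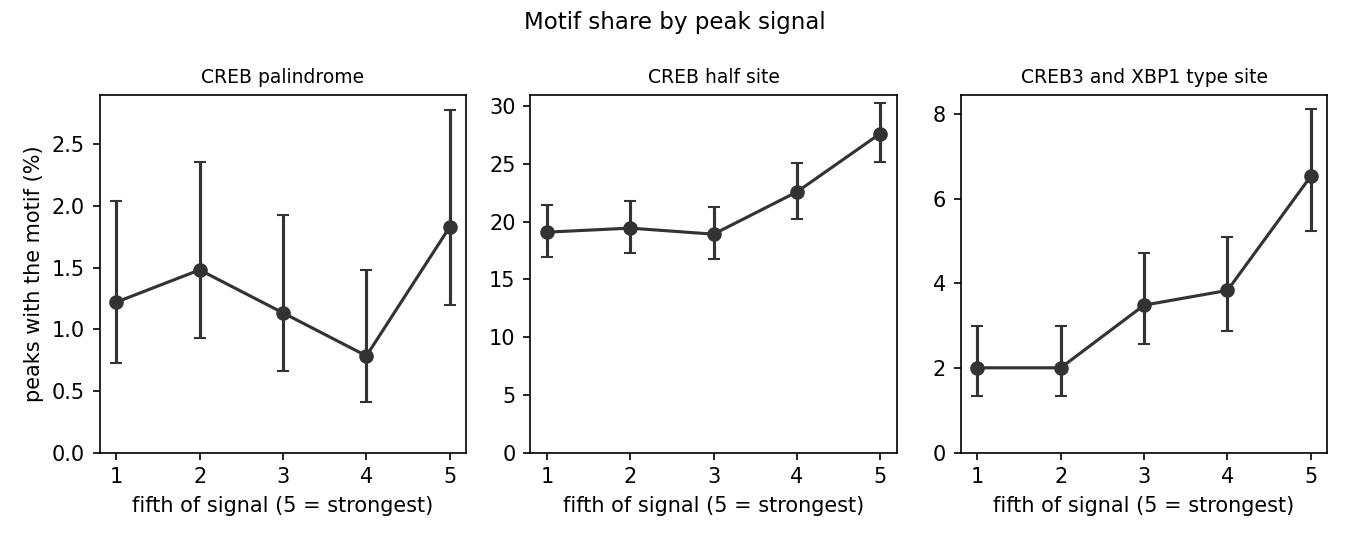
Percent of peaks with each CREB-type motif (vertical, with Wilson 95% intervals) by quintile of pooled signal (horizontal, 5 the strongest), with 1147 peaks in each. TGACGTGK rises from 2.01% to 6.54%.

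Among 32891 sequences of 8 bases, 4070 were more and 2635 less frequent at summits than in flanks (Fisher's exact test, Benjamini-Hochberg adjusted). The smallest p belonged to AGACGCAG, found at 494 summits (8.61% against 0.471%, odds ratio 19.9, exact adjusted p = 5.7e-170). GAGACGCA, GACGCAGA and AGAGACGC, which overlap it, had odds ratios of 17.7, 19.5 and 17.3, and GAGAGAGA followed. None of these 5 holds the CREB core TGACG. Against GC-matched promoter windows 1185 sequences were raised, of which 1069 were also raised against the flanks. There the odds ratios were 6.66 for AGACGCAG, 7.81 for GAGACGCA, 6.38 for GACGCAGA and 11.3 for AGAGACGC, and each passed.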

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

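The replicated list left out some regions that were among the 5735 strongest in both libraries. Among the 5735 strongest regions of each replicate, 32 of replicate 1 overlapped one of replicate 2 but no replicated peak. Most of these ranked in the lower part of the 5735 regions of replicate 1, down to rank 5664. Those with the best ranks, 552 and 640, overlap each other on IV and both met a replicate 2 region of signal 185. The 32 regions are a signal outside the list that the comparisons use.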

How the results depend on the processing

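Choices were changed 1 at a time, except that motif windows of 100 bp to each side came with flanks at 500 bp, the nearest 5′ end with a limit of 2000 bp, and promoters without a peak with matching on GC content. Alternatives with 1 gene per promoter peak, with peaks in or outside promoter windows alone, and those of replicate 1 against 2 were chosen after the data were examined, and the rest before. The promoter share stayed above random placements under every promoter window, in the 2867 strongest peaks and in each replicate alone, from 46.5% to 71.9%. A stricter IDR was not run because the lists give none per region, the loci were not looked up on ce10 because no annotation of it was used, and the strongest pooled regions are the replicated peaks themselves. No paired analysis was possible because there was 1 group.

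Overlap of the replicated peaks with replicates 1 and 2 moved to 86.8% and 84.4% with summits within 100 bp, and to 99.9% and 99.5% with all 30000 regions. Those 30000 include background, and no share under random placement is given for them. Replicate 1 against 2 gave 75.9% with 50% of the region covered and 72.2% with summits within 100 bp. The odds ratio of X over autosomal promoters was 1.11 to 1.14 without either replicate. Raised sequences of 8 bases fell to 1185 against GC-matched promoters and 2541 in the 2867 strongest peaks, the latter with fewer windows to test.

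Body wall muscle had an odds ratio of 1.19 with the narrow window, 1.32 in the strongest peaks and 1.21 with 1 gene per peak. Hypodermis had 1.37 with the wide window, 1.30 by the nearest 5′ end and 1.01 with 1 gene per peak, but 0.713 with the narrow window, 0.317 in the strongest peaks and 0.562 to 0.778 without either replicate. Histones had 0.762 by the nearest 5′ end and 0.853 with 1 gene per peak. Rotation compares with random positions and not with other genes. It left 1 list low, the chemoreceptors, and 12 high against 9, the added ones being neurons (ratio 3.14), pharynx (1.97) and histones (3.39). The ratio of bound genes to the mean of rotations was 1.16 for collagens, 1.81 for hypodermis, 1.70 for muscle and 1.38 for germline.

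Odds ratios of motifs that turned across 1 were mostly of rare sites. With 25 bp windows they were 0.499 for TTACGTAA and 0.998 for TGRACTTTG. With 100 bp windows and flanks at 500 bp they were 1.45 for TGASTCA (exact adjusted p = 0.000777), 0.887 for TTACGTAA and 1.07 for WWTRTCAT, while TGACGTCA had 1.97, TGACGTGK 6.41 and CACGTGG 2.59 and still passed. Against GC-matched promoters they were 1.44 for TGASTCA, 0.545 for TTACGTAA, 0.991 for GGGCGG, 1.49 for WWTRTCAT (exact adjusted p = 6.81e-05), 0.958 for TGRACTTTG and 0.833 for AGTCGACT. In the strongest peaks TGASTCA had 1.07 and AGTCGACT 0.495. In promoter peaks alone TGASTCA had 1.11 and AGTCGACT 0.985, and outside promoters TTGCGCAA had 0.782 and WWTRTCAT 1.05. Without either replicate TGASTCA had 1.09 to 1.22 and AGTCGACT 0.534 to 1.30. The cause of these changes was not tested. Over all alternatives but rotation, 113 odds ratios of lists, 93 of motifs and 20 of the named sequences of 8 bases kept their direction and side of the threshold. Of lists 8 changed direction, and 2 gained and 3 lost a call in the same direction. Of motifs 20 changed direction, and 3 gained and 4 lost a call in the same direction. Values of the named genes were less stable, with 69 labelled as the same as in the main setting and 65 as moved.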

Other observations

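Peaks were also found at non-coding RNA genes, in a comparison chosen after the data were examined. A summit lay in the promoter window of 265 of 612 tRNA genes (43.3%) against a mean of 43.7 genes when summits were rotated along their chromosomes, and of 140 of 346 snoRNA genes (40.5%) against 23.6. Spliceosomal and other snRNA genes had 31 of 129 against 8.21, lincRNA genes 37 of 194 against 13.4 and microRNA genes 43 of 261 against 18.3. piRNA genes (518 of 15363 against 943) and pseudogenes (47 of 2128 against 134) had fewer than in rotations. Each of these passed (permutation adjusted p = 0.00228), while rRNA genes, 0 of 20 against 1.15, did not (permutation adjusted p = 0.849). These rotations do not keep peaks near genes, and many small RNA genes lie beside or within protein-coding genes. The shares of lincRNA and microRNA genes did not exceed the 19.3% of protein-coding genes.

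The tests at crh-2 were chosen after the absence of regions there was seen. The gap in the pooled list that holds crh-2 ran from II 5151966 to 5217768, 65803 bp with 21 gene starts, and similar gaps of 59799 and 62716 bp were found in replicates 1 and 2, while 46 pooled gaps with 5 or more genes, itself included, were as long. Extra copies of the tagged locus may have disturbed the control or the calls, and this stays open, since a gap made that way need not be among the longest and the copy number was not measured. A stretch with few regions anyway also stays open, since 2.69% of 9388 random windows of that length with as many gene starts held no pooled region, between the bounds of 5% and 1% set for it. No biological explanation was tested.

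Among promoter peaks, TGACGTGK was more frequent at those of ER and secretory genes than at others. Most of the 205 summits with TGACGTGK lay elsewhere. It was found at 11 of 53 of their promoter peaks (20.8%) and at 2.58% of other promoter peaks, an odds ratio of 9.89 (95% interval 4.92 to 19.9, Fisher's exact p = 1.72e-07). GC content as the whole cause is argued against, since the odds ratio against GC-matched promoter peaks was 13.2 (5.16 to 33.5). No match on signal was made, and the share with the site also rose with signal, to 6.54% in the strongest quintile. Of the named ER and secretory genes, crt-1 and rab-1 held the site at their peak. The peaks of hsp-3, pdi-3, sec-61.G and copd-1 did not. At ribosomal protein genes 0 of 67 peaks held the site, an odds ratio of 0.244 whose interval of 0.015 to 3.97 leaves it open whether they differ from other promoters. XBP1 and other factors share this site, so which factor is bound through it was not tested.

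The larger share of X peaks outside promoter windows may come in part from the smaller part of X that promoter windows cover, 22.7% against 28.03% of autosomal bases. Divided by that share, the promoter share on X was 0.993 times that on the autosomes (95% interval 0.93 to 1.06). This ratio uses promoter shares only. It does not show by itself whether X sequence outside promoter windows held more peaks for its length. Such peaks numbered 604 on the 17718942 bp of X and 391 on the 17493829 bp of IV. Promoter windows covered 22.7% of X and 26.7% of IV, so X held more of them for its length than IV. Counts on the autosomes ran from 342 on I to 399 on III. What part of the larger share coverage explains was not computed. GAGAGAGA is argued against, with an odds ratio of 0.404 on X against the autosomes outside promoters (0.263 to 0.62). GCGCAGGG, the core of the motif known at X sites that recruit the dosage compensation complex, was at 10 of 604 X peaks and 1 of 1822 autosomal peaks outside promoters (odds ratio 30.7, Fisher's exact p = 7.39e-06), too few for the whole excess. Among the 100 strongest peaks it was at 7 of 16 X peaks and 0 of 19 autosomal peaks outside promoters (Fisher's exact p = 0.0017, chosen after the data were examined), so recruitment sites are a candidate source of strong X signal, which these lists do not separate from binding of CRH-2.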
